A study of Caenorhabditis elegans with 6 samples.

How the data were processed

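Whole Caenorhabditis elegans larvae of 2 genotypes, wild-type and zip-3(gk3164), were profiled on 6 Affymetrix arrays, 3 per genotype. Per the labels, a bleach treatment synchronized the worms, which grew in liquid on control RNAi bacteria up to the L4 stage, total RNA was extracted with an organic reagent, and biotin-labelled cRNA was made with a 3' in vitro transcription kit. The values used are probe set intensity values on a linear scale, made by the authors with MAS5 and Affymetrix Expression Console, per the submitters' processing notes, and the versions of both are not given in the sources used here. In every column the mean without the lowest and highest 2% of values was 500.2, so each array had been scaled to a common mean. The table held 22625 probe sets, of which 77 were array controls. No detection calls and no scanner images were used here, so a filter on signal stands in for detection.

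MAS5 subtracts mismatch probe signal, which makes dim probe sets noisy on the log scale, and a single scaling factor per array leaves differences in the shape of the distributions in place. Signals were transformed to log2 with no added constant and no further normalization between arrays. Probe sets were tested where their mean log2 value over the 6 arrays reached the 40th percentile of the 22548 probe sets that were not controls, a signal of 68.7, which left 13529. Genotypes were compared with limma 3.58.1 in R 4.3.3, by a linear model on genotype and empirical Bayes moderation with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Differences are mutant minus wild-type, and each is given with the moderated standard error. Probe sets were named through the platform annotation, which gave 1 gene for 20766, several for 887 and none for 895. For 20701 the gene identifier matched the gene table of assembly WBcel235, which changed 0 symbols. No gene was named from a probe set with several genes. A gene was represented by its probe set with the highest mean over the 6 arrays, and 10369 genes were tested. Suffixes for shared sequence marked 5380 of the tested probe sets. Genes with called probe sets of opposite sign numbered 0.

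Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 of 36 lists that had at least 5 tested members. The lists covered mitochondrial, endoplasmic reticulum and cytosolic stress responses, immunity, detoxification, metabolism, ribosomes and proteasome, transcription factor families, germline, sperm, yolk and embryonic genes, cuticle and moulting, and markers of muscle, neurons, intestine, pharynx, vulva and males. Of the 11 calls, 8 higher and 3 lower, 0 held with an estimated correlation, where the lowest adjusted p was 0.783. Estimated correlations within a list are high where genes vary together between arrays of one genotype, and reached 0.98 among the vitellogenins and 0.90 among the sperm genes. They were low in other called lists, at 0.03 for bZIP genes, 0.04 for the mitochondrial unfolded protein response and 0.06 for vulva and uterus. The loss of those calls therefore does not show that their genes vary together. limma's fry, which tests whether the genes of a list move on balance in one direction and does not compare them with other genes, called 1 list, vulva and uterus (adjusted p = 0.0432), and its test for change in either direction called 13. Counts of list members are given over all probe sets tested and adjusted over the list alone.

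The lists, tests, filters, alternatives and the rule for named genes were fixed before the data were examined. The rule named zip-3, then the genes with adjusted p under 0.05 whose mutant arrays all lay on the same side of the wild-type arrays, up to 12 in each direction by size and at most 3 from a family and 4 with only a sequence name, with the 5 smallest p-values taken where fewer than 5 genes passed. It also named up to 4 members of each described list by the size of the moderated statistic, and hsp-6, hsp-60 and atfs-1 whatever their values. It gave 12 higher and 5 lower genes. The alternatives were quantile normalization, centring each array on its median, an offset of 16, no filter, a filter at the 60th percentile, empirical Bayes without trend or with robust estimation, array weights, replicate number as a block, leaving out each array, leaving out probe sets of shared sequence, averaging the probe sets of a gene, and camera with an estimated correlation. Settings added after seeing the data were a threshold of 0.1 and the sperm list with probe sets that match several sperm genes.

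The fits were tested on simulated arrays, 3 against 3, with 13529 probe sets and 50 changed at each size. The mutant against wild-type fit recovered 16% of changes of 1 on the log2 scale, 74% of changes of 2, 90% of 3 and 94% of 4, with 3 false calls among 140. Camera called 0 of 10 unchanged simulated lists of 40 genes. The simulated noise was independent between probe sets, while genes of several real lists varied together. These counts therefore do not show the error rate of the calls or of camera on the real arrays. The labels call the samples biological replicates without naming separate cultures, so p-values measure the spread between these samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.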

Results

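Transcript levels were measured in whole Caenorhabditis elegans of 2 genotypes, wild-type and zip-3(gk3164), with 3 Affymetrix arrays for each genotype and 6 arrays in all. zip-3 encodes a bZIP transcription factor that has been linked to repression of the mitochondrial unfolded protein response, the program by which worms raise mitochondrial chaperones and proteases under mitochondrial stress. The synchronized worms grew in liquid, ate bacteria of the control RNAi culture, and were collected as L4 larvae, the last larval stage. The comparison asked which transcripts differed in level between mutant and wild-type larvae under these conditions. Values are linear MAS5 signals, and the median signal of an array lay between 124.7 and 139.6. Of 22548 probe sets that were not controls, 13529 were bright enough to be tested, and they represented 10369 named genes. The number of arrays limits the precision of every value given here.

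The brighter of the 2 probe sets for the zip-3 transcript was lower in each of the 3 mutant arrays than in any wild-type array. It had a mean signal of 1085.4 ± 134.2 in wild-type and 359.0 ± 114.6 in the mutant (SD, n = 3 each). The wild-type arrays read 1203.9, 1112.7 and 939.6 for zip-3, and the mutant arrays 384.6, 458.7 and 233.8. The log2 difference of zip-3 was -1.64 ± 0.28 (SE), a 3.13-fold lower signal on the linear scale, and it did not pass the threshold over all probe sets (limma adjusted p = 0.0717). A two-sided exact permutation test of zip-3 alone gave p = 0.10, the smallest value that 3 arrays against 3 can give. The dimmer zip-3 probe set read 91.06 ± 23.14 and 63.36 ± 12.08, with mutant array 2 at 74.89 above wild-type array 3 at 71.93, a log2 difference of -0.51 ± 0.30 (limma adjusted p = 0.393). Whether either probe set lies within the deleted part of the gene was not known from the labels, so a remaining zip-3 signal does not show an intact transcript. Without mutant array 3, the zip-3 difference was -1.36 and passed (limma adjusted p = 0.00645), and over 15 alternatives the adjusted p of zip-3 ranged from 0.00164 to 0.300.

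**Figure D1:**
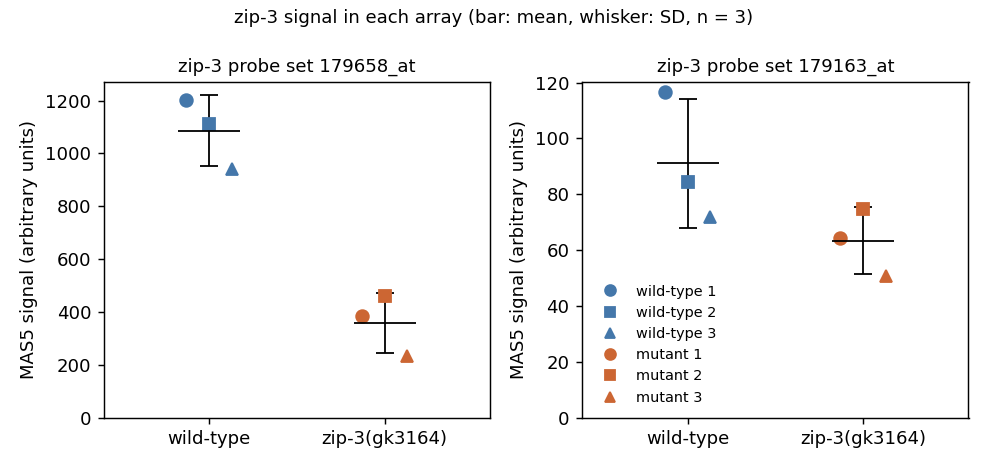
MAS5 signal (arbitrary units, linear axis from 0) of the 2 zip-3 probe sets in each array, with the horizontal bar at the mean and the whisker giving the SD over 3 arrays. For the brighter probe set the mutant arrays lie at 233.8 to 458.7, below the wild-type arrays at 939.6 to 1203.9.

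The arrays did not fall into 2 tight groups by genotype. The 3 wild-type arrays correlated with one another at r = 0.954 to 0.972 across the tested probe sets, where probe sets are not independent replicates. Mutant arrays 1 and 2 correlated at 0.956, while mutant array 3 correlated with them at 0.925 and 0.890 and with the wild-type arrays at 0.943, 0.953 and 0.958. The first principal component held 61.8% of the variance and placed mutant array 1 at 46.2 and mutant array 2 further out in that direction, the wild-type arrays at -50.2, -34.4 and -23.4, and mutant array 3 at -13.1. The second component held 12.7% and set mutant array 3 apart, at 40.6. Medians of the individual mutant arrays are therefore given for the gene lists that passed.

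Of the 14 genes that rose in zip-3(gk3164), 4 belong to the list of moulting genes, dpy-6, lpr-3, let-653 and mlt-11, and 2 are cuticle collagens, col-41 and col-176. dpy-6, whose mucin-like product is needed for normal body shape, rose from a signal of 129.8 ± 44.2 to 1432.7 ± 438.1 (SD, n = 3), a log2 change of 3.47 ± 0.34 (SE). mlt-11, which encodes a protease-inhibitor-like protein needed for moulting, rose from 478.5 ± 180.3 to 3388.7 ± 734.6, or by 2.89 ± 0.33, and its other called probe set gave 2.93 ± 0.34. The lipocalin gene lpr-3 rose by 2.81 ± 0.28 and let-653, which encodes a zona pellucida domain protein of the apical matrix, by 2.55 ± 0.28. The collagen genes col-41 and col-176 rose by 3.12 ± 0.35 and 2.53 ± 0.29. sym-1, which encodes a secreted leucine-rich repeat protein, rose by 2.76 ± 0.30, and the cadherin gene cdh-7 by 2.56 ± 0.32. The sym-1 difference ranged from 1.80 to 3.00 over 16 alternatives. srap-1 rose by 2.34 ± 0.23 with both of its called probe sets at 2.34, and strm-1, which encodes a sterol methyltransferase, rose from a signal of 38.27 ± 9.75 to 185.5 ± 14.5. T14B4.5 and F53B3.6, known here by sequence name only, rose by 2.45 ± 0.25 and 2.41 ± 0.27. nlp-31, an epidermal antimicrobial peptide gene, rose from 225.2 ± 24.4 to 898.4 ± 67.2, or by 2.00 ± 0.19. A second lipocalin gene, lpr-1, rose by 2.26 ± 0.24, and it is named here after its value was seen. The probe sets of mlt-11, lpr-3, nlp-31, col-41 and T14B4.5 carry suffixes for sequence shared with other transcripts, so related genes can add to their signals.

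Far fewer genes fell at the adjusted threshold on all 6 arrays. That balance did not hold at an unadjusted limma p under 0.05, with 1023 genes higher and 1044 lower, or without mutant array 3. hrg-7, which encodes a secreted protease-like protein that acts in heme signalling, fell from 8558.6 ± 2139.1 to 1529.9 ± 625.4, a log2 change of -2.53 ± 0.32. The UDP-glucuronosyltransferase gene ugt-13 fell from 383.3 ± 85.8 to 90.3 ± 14.6, a log2 change of -2.07 ± 0.26. No named gene passed in every alternative. hrg-7 passed in 3 of 16 and ugt-13 in 6 of 15, and among the genes that rose cdh-7 passed in 4 of 15, strm-1 in 5 of 15, let-653 in 8 of 15 and the others in 9 or 10 of up to 16. The next smallest p-values among lower genes belonged to K09C6.9 at -1.79 ± 0.26 (limma adjusted p = 0.0579), C30G12.2 at -1.12 ± 0.18 (0.0707) and Y69A2AR.25 at -1.80 ± 0.29 (0.0717), which did not pass. In total 18 probe sets passed an adjusted p of 0.05, 16 higher and 2 lower, and all 18 differed by at least 2-fold. They belonged to 16 genes, 14 higher and 2 lower, with limma adjusted p-values between 0.0364 and 0.0470. At an unadjusted p under 0.05 there were 2623 probe sets, 1369 higher and 1254 lower, where 676 were to be expected if probe sets were independent and unchanged. Other groupings of the same arrays gave 86 to 1923 at that level, the most with mutant array 3 in place of wild-type array 3. Leaving out mutant array 3 gave 2167 probe sets, 807 higher and 1360 lower, and all 16 genes remained called. In mutant array 3 itself, 1780 of the 2167 differed with the same sign, 658 of the higher and 1122 of the lower. Its signal lay within the wild-type range for 723 of them, or 33.4%. The lower set had a median of -0.25 in mutant array 3, against -1.67 in the fit without it. The higher set had a median of 0.58 in mutant array 3, also smaller than in that fit. Leaving out any other array gave 0 probe sets at the adjusted threshold and 1476 to 2398 at an unadjusted p under 0.05.

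**Figure D2:**
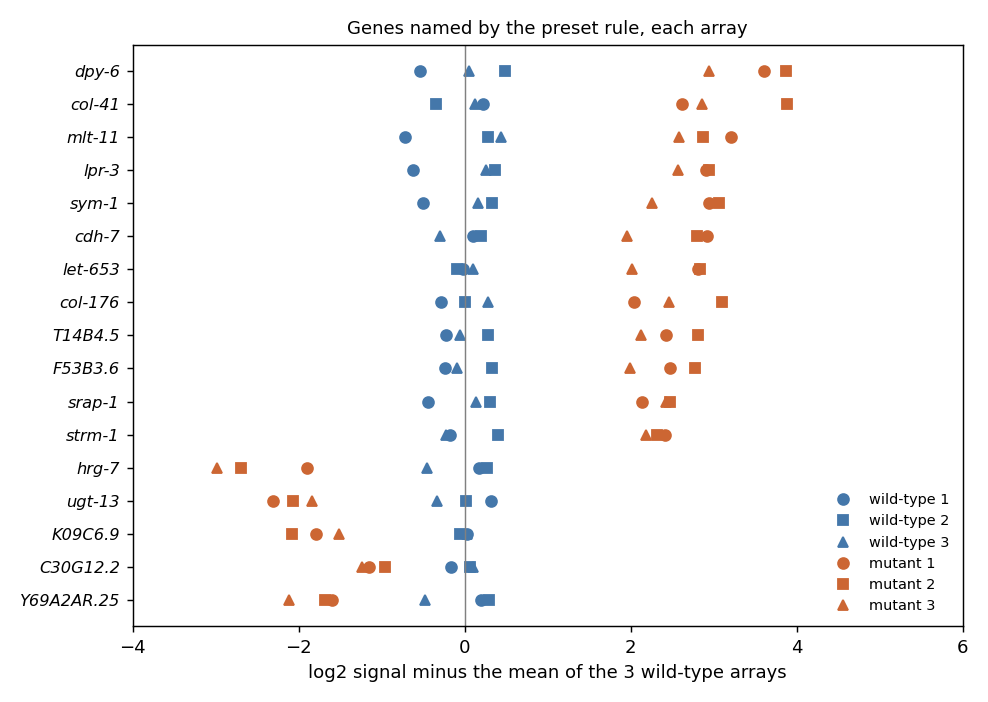
Log2 MAS5 signal minus the mean of the 3 wild-type arrays (horizontal axis, log2 units) for 17 genes, with wild-type arrays in blue and mutant arrays in orange and the marker shape giving the array number. For all 17 genes the 3 mutant arrays lie on the same side of the 3 wild-type arrays, and K09C6.9, C30G12.2 and Y69A2AR.25 did not pass the adjusted threshold.

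Genes of the moulting cycle were higher as a group in the mutant. Of 41 tested members, 38 had a positive log2 difference, and the median was 1.33 (limma camera adjusted p = 3.97e-14; adjusted p = 0.783 with an estimated correlation). Over all genes tested, 4 members rose, dpy-6, lpr-3, let-653 and mlt-11, and adjusted over the list alone 24 rose and 0 fell. nhr-25, a nuclear receptor gene required for moulting, was among the 24, with a log2 difference of 1.74 ± 0.24 and a signal of 120.2 ± 22.9 in wild-type and 402.1 ± 72.8 in the mutant (SD, n = 3). Over 15 alternatives the nhr-25 difference ranged from 1.08 to 2.04. The 3 mutant arrays stood at list medians of 1.43, 1.41 and 0.90 relative to the wild-type mean. The wild-type arrays themselves ranged from -0.75 through 0.16 to 0.54, a spread nearly as wide as the difference between genotypes. Without wild-type array 1 the list median was 0.82 with the call kept, and leaving out single arrays gave 18 to 27 members higher over the list alone. Over all genes tested 19 members rose without mutant array 3 and 0 without any other.

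Cuticle collagens did not shift as a family, because members moved both ways. Of 114 tested collagen genes, 57 were positive and 57 negative, with a median of -0.00, a mean of 0.02 and a camera test directed downward (adjusted p = 0.328; adjusted p = 0.919 with an estimated correlation). Adjusted over the list alone, 10 collagens rose and 3 fell, and over all genes tested 2 rose, col-41 and col-176. The balance depended on mutant array 3, without which 15 rose and 26 fell over the list alone and 12 rose and 21 fell over all genes tested, while without any other array 8 to 11 rose and 1 to 3 fell over the list alone. Among the 10 were dpy-3 at 1.98 ± 0.27 and dpy-7 at 1.87 ± 0.32, both needed for normal body shape. The 3 that fell over the list alone, named here after their values were seen, were col-150 at -2.13 ± 0.36, col-12 at -0.69 ± 0.15 and dpy-13 at -0.56 ± 0.12. The family median was -0.27 and passed without wild-type array 1 (adjusted p = 0.0134), was -0.16 and passed without mutant array 2 (0.0318), and was 0.14 without wild-type array 3 (0.559), and over 17 alternatives the adjusted p ranged from 0.0134 to 0.774.

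Sperm genes were lower in the mutant as a group, and the size of the difference varied widely between the mutant arrays. All 50 tested members, mostly major sperm protein genes and other spermatogenesis genes, had a negative log2 difference, with a median of -1.38 (limma camera adjusted p = 1.92e-20; adjusted p = 0.783 with an estimated correlation). Mutant arrays 1, 2 and 3 stood at list medians of -1.55, -2.29 and -0.30, against 0.10, 0.05 and -0.11 in wild-type. Adjusted over the list alone 43 members fell, and over all genes tested 0 did. ssp-10 averaged 5142.3 in wild-type and 1866.8 in the mutant (-1.63 ± 0.41), msd-2 12359.3 and 4695.0 (-1.60 ± 0.42), and spe-26 394.4 and 163.1 (-1.36 ± 0.37). The probe sets of ssp-10, msd-2 and spe-26 carry suffixes for shared sequence, so members of the list need not be separate measurements. The counts of members that fell depend on the array set. Without mutant array 3 the median was -1.97, 48 members fell over the list alone and 47 over all genes tested, and without any other single array 0 members passed over the list alone. Another 16 probe sets that each match several sperm genes were all lower, and with them the median over 66 members was -1.36. Over 17 alternatives with the preset correlation, the camera adjusted p of the sperm list ranged from 1.74e-28 to 2.71e-04.

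Oocyte and germline genes and the yolk protein genes were also lowest in mutant array 2, with mutant array 3 among the wild-type arrays. Of 48 tested oocyte and germline genes, 45 were negative, with a median of -0.91 (camera adjusted p = 2.22e-10; adjusted p = 0.783 with an estimated correlation). Their medians were -0.84, -1.81 and -0.11 in mutant arrays 1, 2 and 3, against 0.11, 0.26 and -0.38 in wild-type. No member passed by itself, adjusted over the list alone or over all genes tested, and 16 had an unadjusted limma p under 0.05. pgl-1 and pgl-3, which encode P granule components, differed by -0.95 ± 0.30 and -0.84 ± 0.31, and the maternal regulator pie-1 by -1.29 ± 0.41. Without mutant array 2 the germline median was -0.47, and without mutant array 3 it was -1.29 with 41 members lower over the list alone and 29 over all genes tested. All 5 vitellogenin genes tested were negative, with a median of -0.73 (camera adjusted p = 0.0211; adjusted p = 0.783 with an estimated correlation), and 0 passed over the list alone. Their array medians were -0.68, -1.52 and 0.02 in the mutant and 0.16, -0.08 and -0.11 in wild-type, and vit-6 averaged 30879.1 in wild-type and 20392.2 in the mutant (-0.68 ± 0.28). The vit-6 probe set carries a suffix for shared sequence. The vitellogenin call was lost without mutant array 2 (median -0.35, adjusted p = 0.0550) and under quantile normalization (0.0510), within a range of 0.00340 to 0.0550 over 16 alternatives, and without mutant array 3 the median was -1.11 with all 5 lower over the list alone.

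**Figure D3:**
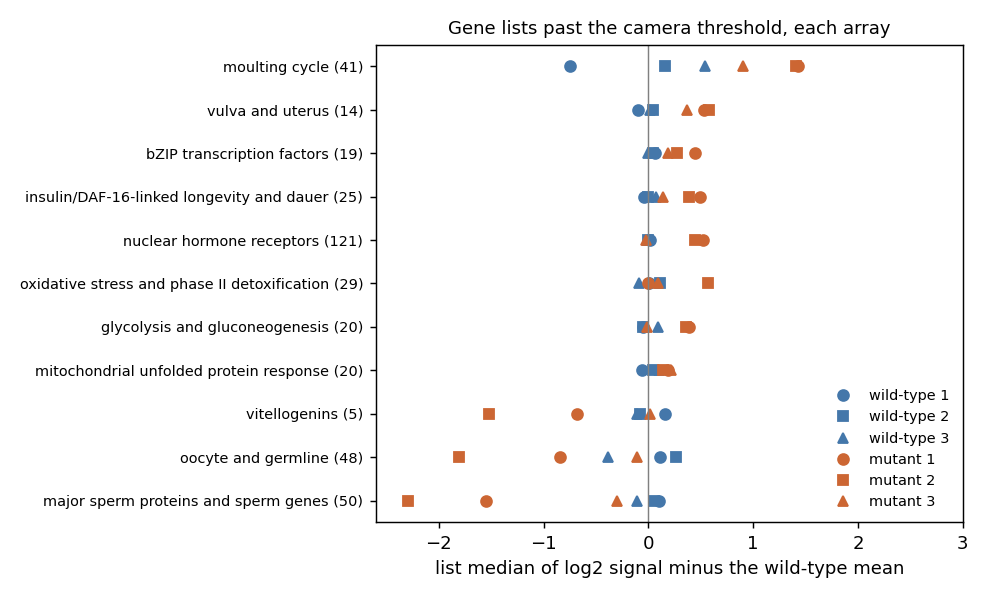
Median over each gene list of the log2 signal minus the wild-type mean (horizontal axis, log2 units) in each of the 6 arrays, for the 11 lists that passed the camera test with the preset correlation, with the number of tested genes in brackets. In the sperm list mutant arrays 1, 2 and 3 stand at -1.55, -2.29 and -0.30, and in the moulting list at 1.43, 1.41 and 0.90.

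The mitochondrial unfolded protein response, the program that zip-3 has been linked to, was shifted upward by a small amount. Of 20 tested members 15 were positive, with a median of 0.23 (camera adjusted p = 0.0486; adjusted p = 0.783 with an estimated correlation). The 3 mutant arrays stood at 0.19, 0.14 and 0.22, against -0.06, 0.04 and 0.10 in wild-type, so the highest wild-type array lay close to the lowest mutant array. No member passed by itself, adjusted over the list alone or over all genes tested, and 1 had an unadjusted limma p under 0.05. hsp-6, the mitochondrial Hsp70, averaged 4070.8 ± 598.1 in wild-type and 5265.9 ± 513.3 in the mutant, a log2 difference of 0.38 ± 0.16 (limma adjusted p = 0.265). The chaperonin gene hsp-60 averaged 3787.0 and 3732.7 (-0.02 ± 0.18), and atfs-1, which encodes the activator of the response, 346.9 and 401.7 (0.21 ± 0.21). The mitochondrial thioredoxin gene trx-2 differed by 0.37 ± 0.16, the protease gene ymel-1 by 0.42 ± 0.18 and gpd-2 by 0.29 ± 0.14. The list's call held in 8 of 17 alternatives, with adjusted p-values from 0.0161 to 0.144, and was lost without wild-type array 1 (0.144), without mutant array 3 (0.0720) and when arrays were centred on their medians (0.0804).

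The lists of immune, C-type lectin, cytosolic heat shock and endoplasmic reticulum stress genes did not pass the camera test. The 10 tested genes linked to ATFS-1 in immunity and detoxification had a median of 0.23 (camera adjusted p = 0.312), with ugt-61 rising over the list alone from a signal of 181.8 ± 2.1 to 393.3 ± 72.7 (SD, n = 3), and irg-1 at -1.70 ± 0.69. Among 36 tested pathogen response genes the median was 0.22 (0.117), and over the list alone 3 rose and 1 fell. nlp-31 and the antimicrobial peptide gene cnc-3 at 2.38 ± 0.55 were among the 3, and irg-2 at -2.18 ± 0.56 was the gene that fell. The pathogen response list passed without wild-type array 1 (0.0210) and without mutant array 1 (0.00176), and without mutant array 2 its median was -0.01 (0.849), within a range of 0.00176 to 0.927 over 17 alternatives. Over that list alone 5 rose and 0 fell without mutant array 1, 1 rose and 3 fell without mutant array 2, and 4 rose and 0 fell without mutant array 3. Without single wild-type arrays 1 to 3 rose and 0 or 1 fell. The 66 tested C-type lectins had a median of -0.03 (0.463), and clec-72 at 1.41 ± 0.25 rose over the list alone; the median was 0.11 without mutant array 3, where 5 rose and 9 fell over the list alone. The 16 cytosolic heat shock genes had a median of 0.03, a mean of -0.07 and a camera test directed upward (0.943), and the median was -0.03 when arrays were centred on their medians. hsp-1 stood at 0.26 ± 0.17 and sip-1 at -1.26 ± 0.60. In the unfolded protein response of the endoplasmic reticulum the median over 27 genes was 0.04 (0.596), with the peptidyl-prolyl isomerase gene fkb-5 at 1.66 ± 0.41 and hsp-4, the BiP chaperone, at -0.45 ± 0.15, and the median was -0.13 without mutant array 2. The heat shock median was -0.02 without wild-type array 3 and -0.00 without mutant array 2. With an estimated correlation the adjusted p of these lists lay between 0.892 and 0.946.

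Several regulatory and metabolic lists were higher by small amounts. The 121 tested nuclear hormone receptors had a median of 0.30, with 19 negative (camera adjusted p = 4.70e-05; adjusted p = 0.825 with an estimated correlation), and array medians of 0.52, 0.45 and -0.02 in the mutant. nhr-25 was the receptor that rose over that list alone, and nhr-91 stood at 1.35 ± 0.25. The receptor median was 0.18 without mutant array 1 and 0.48 without mutant array 3, where 10 rose over the list alone and 13 over all genes tested, against 0 or 1 over the list alone without any other array. The 14 vulva and uterus genes had a median of 0.46, with 11 positive (0.00323; adjusted p = 0.783 with an estimated correlation), array medians of 0.53, 0.58 and 0.37 in the mutant, and 3 rose over the list alone. These were vab-23 at 1.42 ± 0.22, the LIM homeobox gene lin-11 at 1.57 ± 0.28 and the cadherin gene cdh-3, with a signal of 146.3 ± 37.2 in wild-type and 419.6 ± 121.8 in the mutant. The 19 other bZIP transcription factor genes had a median of 0.36, with 16 positive (0.0137; adjusted p = 0.783 with an estimated correlation) and array medians of 0.45, 0.27 and 0.19 in the mutant, and atf-2 at 1.13 ± 0.22 and atf-8 at 1.79 ± 0.39 rose over the list alone. The bZIP call was lost with the filter at the 60th percentile (0.0680; range over 17 alternatives 0.00444 to 0.0680), where the median was 0.21. Single arrays left out gave 3 to 5 vulva and uterus genes and 0 to 3 bZIP genes higher over the list alone.

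Among metabolic genes pck-1, which encodes phosphoenolpyruvate carboxykinase, a gluconeogenic enzyme, was higher in every mutant array. Its mean signal was 1481.6 ± 460.0 in wild-type and 5171.6 ± 1239.1 in the mutant (SD, n = 3), a log2 difference of 1.82 ± 0.26 that did not pass over all probe sets (limma adjusted p = 0.0579). Both lists that hold it passed, with smaller differences in mutant array 3. The glycolysis list stood at 0.39, 0.36 and -0.01 in mutant arrays 1, 2 and 3, the last within the wild-type range of -0.05 to 0.09, and the insulin list at 0.49, 0.39 and 0.14. The 20 glycolysis and gluconeogenesis genes had a median of 0.25, with 16 positive and 2 higher over the list alone, pck-1 and the lactate dehydrogenase gene ldh-1 at 0.82 ± 0.18 (camera adjusted p = 0.0218; adjusted p = 0.783 with an estimated correlation). The 25 insulin and DAF-16-linked longevity and dauer genes had a median of 0.35, with 21 positive and pck-1 higher over the list alone (0.0137; adjusted p = 0.783 with an estimated correlation). In that list daf-16, the FOXO transcription factor of insulin signalling, stood at 0.65 ± 0.18 and daf-9, a steroid hormone synthesis gene, at 1.14 ± 0.31. The daf-16 difference ranged from 0.22 to 0.80 over 16 alternatives. Without mutant array 3, 4 glycolysis genes and 7 insulin genes rose over the list alone, and 3 and 5 over all genes tested, while without any other array 1 or 2 and 1 did over the list alone. Without mutant array 1 the glycolysis adjusted p was 0.129 and the insulin adjusted p was 0.0631, and without probe sets of shared sequence they were 0.511 and 0.237, at medians of 0.19 and 0.38. Over 17 alternatives they ranged from 0.00121 to 0.511 and from 0.00112 to 0.237. The 29 oxidative stress and phase II genes had a median of 0.28, with 23 positive and sdz-8 at 1.75 ± 0.29 higher over the list alone (0.0206; adjusted p = 0.825 with an estimated correlation). That shift stood mostly in mutant array 2, at 0.57, against -0.00 and 0.09 in mutant arrays 1 and 3. Without mutant array 2 its median was 0.01 (0.481), without wild-type array 3 it was 0.24 (0.0679), and with array weights it was 0.07 (0.339; range 3.72e-04 to 0.481), and 0 to 2 members rose over the list alone when single arrays were left out.

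The remaining lists did not pass the camera test, and with an estimated correlation their adjusted p lay between 0.783 and 0.943. Among detoxification enzymes the median was -0.12 for 44 UDP-glucuronosyltransferases (adjusted p = 0.0533), in which over the list alone ugt-61 rose and ugt-13 and ugt-12 fell, 0.27 for 38 cytochrome P450s (0.109), in which cyp-25A1 at 1.42 ± 0.22 rose over the list alone, and 0.17 for 26 glutathione S-transferases (0.328). The UDP-glucuronosyltransferases passed without mutant array 1 (0.00176), without mutant array 2 (0.00322) and without wild-type array 3 (0.0240), their median was 0.06 without mutant array 3, and over 17 alternatives their adjusted p ranged from 0.00176 to 0.929. Over that list alone 1 rose and 5 fell without mutant array 2, 1 rose and 3 fell without mutant array 3, and 0 rose and 1 fell without any other array. The cytochrome P450s passed without mutant array 3 (0.0134; range 0.00485 to 0.654), where 9 rose and 1 fell over the list alone and 6 and 1 over all genes tested, and the glutathione S-transferases without mutant array 1 (0.0103; range 0.0103 to 0.863), with a median of -0.11 without mutant array 2. Among mitochondrial and protein turnover genes the median was 0.06 for 48 respiratory chain genes of the nucleus (0.527), 0.03 for 57 mitochondrial ribosome genes (0.646), -0.05 for 74 cytosolic ribosome genes (0.109), -0.07 for 33 proteasome genes (0.109) and 0.14 for 25 tricarboxylic acid cycle genes (0.0995). The cytosolic ribosome median was 0.10 under quantile normalization and passed in that direction (7.04e-04; range 8.99e-06 to 0.989), while without mutant array 2 it was -0.12 and passed downward, so its direction is not settled. Without mutant array 2 the respiratory chain median was -0.02, the mitochondrial ribosome median was -0.06, and the proteasome list passed (0.00984; range 0.00984 to 0.537). Without mutant array 3 the tricarboxylic acid cycle list passed (0.00329; range 0.00329 to 0.382), where 5 of its members rose over the list alone, and in the respiratory chain list 1 rose and 4 fell. The 2 paralogous succinate dehydrogenase subunit genes of the respiratory chain list differed in sign, sdha-1 at 0.56 ± 0.18 and sdha-2 at -0.83 ± 0.19. The 51 fatty acid metabolism genes had a median of 0.17 (0.527), with the fatty acid synthase gene fasn-1 at 0.69 ± 0.16, and passed without mutant array 3 (0.0346; range 0.0346 to 0.959). The 111 ubiquitin ligase substrate adaptors had a median of 0.01, a mean of -0.06 and a camera test directed downward (0.592), and without mutant array 3, 13 rose and 14 fell over the list alone.

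Markers of other tissues gave medians of 0.22 for 35 neuronal genes (adjusted p = 0.0533), 0.09 for 42 neuropeptide genes (0.646), 0.20 for 43 muscle genes (0.117), 0.02 for 28 intestinal genes (0.695), -0.21 for 25 pharyngeal genes (0.171), 0.26 for 31 histone genes (0.0875) and 0.24 for 6 embryonic genes (0.267). In muscle the twitchin gene unc-22 stood at 1.28 ± 0.29 and the vinculin gene deb-1 at 0.80 ± 0.24, while tni-4 stood at -0.99 ± 0.37. In neurons unc-30 and unc-25, both of GABA neurons, stood at 0.96 ± 0.25 and 0.57 ± 0.19. In the pharynx peb-1 rose over the list alone, from a signal of 79.27 ± 20.78 to 349.0 ± 121.7, while abu-15, abu-11 and abu-10 stood at -1.74 ± 0.54, -1.60 ± 0.53 and -1.37 ± 0.45. Pharyngeal list medians were -0.57, -0.23 and 0.64 in wild-type arrays 1, 2 and 3, and -0.34, -0.21 and -0.17 in the mutant arrays, all within that wild-type range. Over the pharyngeal list alone, 1 gene rose and 7 fell without wild-type array 1, and 1 rose and 5 fell without mutant array 3. Without any other array 0 fell. The linker histone genes his-24 and hil-3 stood at 1.27 ± 0.21 and 1.27 ± 0.29, and both rose over the histone list alone, as his-24 did over the embryonic list alone. Another linker histone gene, hil-4, stood at -0.98 ± 0.34 and his-74 at -0.78 ± 0.23. The neuronal list passed without mutant array 1 (0.0232), without wild-type array 2 (0.0415) and without wild-type array 3 (0.0240), in a range of 0.0232 to 0.262. The histone list passed without mutant array 3 (0.0364) and without wild-type array 1 (0.0381), in a range of 0.0162 to 0.650, and without mutant array 3 it held 7 higher and 4 lower members over the list alone and 6 and 4 over all genes tested. The muscle list passed without mutant array 1 (0.00176) and without wild-type array 3 (6.85e-04; range 6.85e-04 to 0.947), the pharyngeal list without wild-type array 1 (0.0121; range 0.0121 to 0.821), with a median of 0.10 without wild-type array 3 and -0.03 without mutant array 1, and the intestinal list without mutant array 3 (0.00896; range 0.00896 to 0.983), where 6 members rose over the list alone. The intestinal median was -0.08 without mutant array 2 and the neuropeptide median -0.04 without wild-type array 1. Genes of the mitochondrial genome had 0 members on the array, and 4 of 20 genes of males and male tissue were bright enough to be tested, so neither list was tested.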

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

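The 16 genes called on all 6 arrays stayed called without mutant array 3, and 0 did without any other array, and the p-values of 3 arrays against 3 rest on the labels' word that the samples are biological replicates. The threshold of 0.1 and the sperm list with probe sets of several genes were chosen after the values were seen. Where a value moved, the cause was not tested. Of the lists called, 0 held with an estimated correlation. For probe sets the count was 42 with an offset of 16, 4738 with array weights, 29 without probe sets of shared sequence, 190 at an adjusted p under 0.1, and 0 to 2167 when single arrays were left out. For genes it was 32 with the offset, 10 with the filter at the 60th percentile, 3698 with array weights, 9 with averaged probe sets, 149 at an adjusted p under 0.1, and 0 to 1758 when single arrays were left out. Array weights gave mutant array 1 a weight of 5.89 and mutant array 3 a weight of 0.27, so the large counts under weights rest mostly on 1 mutant array. Same-numbered arrays did not pair, with correlations of 0.02, 0.05 and -0.16 between deviations from the genotype means, the last -0.04 without a filter. Replicate number as a block gave 0 probe sets and 0 genes. With it the pharyngeal list (camera adjusted p = 0.0354, range 0.0121 to 0.821) and the UDP-glucuronosyltransferases (0.0469) passed. The call of the mitochondrial unfolded protein response list was lost with it (0.0554). Wild-type arrays 1, 2 and 3 correlated best with mutant arrays 3, 1 and 2, at 0.25, 0.08 and 0.24. The zip-3 transcript stood at -1.54 with array weights and at -1.85 to -1.36 when single arrays were left out, and hsp-60 at 0.16 with weights and -0.14 to 0.08. The cytosolic heat shock median, 0.03, was -0.03 with median centring, 0.06 without a filter, 0.03 without trend, -0.01 with array weights, 0.03 with the block and -0.04 with averaged probe sets, the direction of its test or median turning in each. With array weights the median was -0.08 for glutathione S-transferases, 0.09 for UDP-glucuronosyltransferases and 0.02 for ubiquitin ligase adaptors, which stood at 0.11 without a filter. Over 17 alternatives the muscle median ranged from -0.01 to 0.39. Neuropeptides stood at 0.06 without a filter and 0.07 without shared-sequence probe sets, and cytosolic ribosome genes at 0.10 under quantile normalization. Leaving out single arrays moved medians that turned, in the median or the test, over -0.07 to 0.11 for C-type lectins, -0.02 to 0.09 for heat shock, -0.13 to 0.17 for the endoplasmic reticulum response, -0.29 to 0.06 for UDP-glucuronosyltransferases, -0.11 to 0.29 for glutathione S-transferases, -0.02 to 0.17 for the respiratory chain, -0.06 to 0.14 for the mitochondrial ribosome, -0.12 to 0.00 for the cytosolic ribosome, 0.01 to 0.29 for fatty acid metabolism, -0.27 to 0.14 for collagens, -0.08 to 0.20 for the intestine, -0.04 to 0.14 for neuropeptides, -0.01 to 0.32 for pathogen response, -0.40 to 0.10 for the pharynx and -0.06 to 0.05 for ubiquitin ligase adaptors.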

Other observations

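Of the tests below, those of RNA degradation, of wild-type RNA in mutant sample 3 and of a noisy array were chosen only after the result was seen, as were the arrays compared in the timing tests and the gene families, formed from shared name prefixes. With an estimated correlation every family had an adjusted p of 0.998, so none of the calls below held. Among 140 families of at least 8 tested genes, the patched-related ptr genes stood at a median of 0.69 with 15 of 18 positive (camera adjusted p = 0.00181; adjusted p = 0.998 with an estimated correlation) and mutant arrays at 0.71, 0.71 and 0.53, and the hedgehog-related wrt genes at 0.66 with 8 of 9 positive (0.00329; 0.998) and mutant arrays at 0.94, 1.01 and 0.31. Several ptr and wrt genes are also members of the moulting list, so both families partly repeat its result. All 11 bus genes, several of which act on the cuticle surface, were positive, with a median of 0.77 (0.00541; 0.998) and mutant arrays at 0.97, 1.04 and 0.32, and the cuticlin-like cutl genes stood at 0.59 with 10 of 12 positive (0.0309; 0.998) and mutant arrays at 0.60, 0.70 and 0.50. In 79 unc genes, a name given for uncoordinated movement, 74 were positive, with a median of 0.40 (6.91e-07; 0.998) and mutant arrays at 0.32, 0.39 and 0.40. The abu genes stood at -1.49 with 2 of 9 positive (0.0309; 0.998) and mutant arrays at -2.01, -1.36 and -0.88, and the neprilysin nep genes at -0.65 with 5 of 16 positive (0.0372; 0.998) and mutant arrays at -0.66, -0.85 and -0.13. Several abu genes are also members of the pharyngeal list, and their wild-type signals differed widely between arrays. abu-15 read 1817.9, 2476.8 and 6820.6 in wild-type arrays 1, 2 and 3, and 518.4, 1218.2 and 1308.9 in the mutant arrays.

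Of 40 protein-coding neighbours of zip-3 in assembly WBcel235, 20 on each side, 21 were tested, and 0 changed (lowest limma adjusted p = 0.178). The insulin-like gene ins-37 stood at -1.40 ± 0.43 and Y39G8B.2 at 1.32 ± 0.51, the 2 with an unadjusted limma p under 0.05.

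Higher moulting genes with lower sperm, germline and yolk genes may reflect cultures that stood at different points within the L4 stage. Across the tested sperm, germline and yolk genes, the difference of mutant arrays 2 and 3 correlated with that of mutant array 1 and wild-type at r = 0.67 (95% interval 0.54 to 0.76). All tested genes gave 0.63, and the nearness of mutant array 3 to wild-type raises both under any cause, so this does not count for timing. Across 41 moulting genes, the difference of wild-type arrays 3 and 1 correlated with that of the mutants and wild-type array 2 at r = 0.11 (-0.21 to 0.40), against 0.37 over all tested genes. That lies under the bound of 0.2 set before the correlation was computed. It does so by less than its standard error, a requirement applied after the value was seen. Both intervals and that standard error treat genes as independent. Genes of these lists varied together, with estimated correlations of 0.58 for moulting, 0.90 for sperm, 0.81 for germline and 0.98 for yolk genes. The intervals are therefore likely too narrow. A correlation across genes leaves out a shift that they share, so it cannot count against timing. Such shifts were seen between arrays of one genotype. Wild-type array 3 minus wild-type array 1 had a median of 1.24 over the moulting genes, against -0.05 over all tested genes. Mutant array 2 minus mutant array 3 had a median of -1.77 over the sperm, germline and yolk genes, against -0.04. In the sperm list the wild-type arrays differed little, at 0.10, 0.05 and -0.11. Timing is left undecided. Whether timing also moved the other lists that passed was not tested, so their differences cannot be taken as separate from it. Mutant array 3 stood near wild-type in the receptor list at -0.02 and the glycolysis list at -0.01, but above it in the vulva and uterus list at 0.37.

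The same pattern could also come from RNA quality or array scaling. In the log2 of the 3' to 5' ratio of control transcripts, 0 of mutant arrays 1 and 2 lay outside the wild-type range of 1.73 to 2.01 for the mean over 4 transcripts. Their actin log2 ratios, 0.92 and 0.86, lay above the wild-type 0.63 to 0.76, so a difference in RNA quality stays open. Under quantile normalization the moulting median was 1.30 and the sperm median -1.38. The arrays had already been scaled to a common mean, and their log2 medians lay between 6.96 and 7.13, so that outcome was nearly fixed in advance. Array medians that close leave little room for array-wide scaling to give list shifts of this size. A mutant that grows at another pace and cultures staged unequally would both give this pattern, and these 6 arrays do not separate them.

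Mutant array 3 near wild-type in sperm, germline and yolk genes might be a sample with wild-type RNA in it. Its zip-3 signal was 233.8, the lowest of all arrays, where the share of 74.1% needed for its sperm genes would give 913.5, so that explanation is ruled against. A poorer sample stays open, since its highest correlation with another array, 0.958, lay only just above the lowest of the others, 0.956 to 0.972, and its mean 3' to 5' log2 ratio, 2.15, was the highest of the 6 arrays and above the wild-type range. For the count of 18 probe sets, 1 of 10 splits of the arrays gave as many, the real one, and the highest other gave 0, but 10 splits are too few for a share under 0.05.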
